A study of Capra hircus with 3 samples.

How the data were processed

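RNA was sequenced from the longissimus dorsi of goats at 3 postnatal stages, kid (2 months), youth (9 months) and adult (24 months), with 1 library per stage. Libraries were prepared from total RNA by standard Illumina protocols, per the labels' protocols. The authors deposited 1 table of FPKM (fragments scaled to gene length and to the mapped total), with 1 column per stage. FastQC, TopHat2 and DESeq were named without version, role or order, per the submitters' processing notes. The genome build, the annotation, the counting method and the treatment of reads matching several genes are not given in the sources used here. Reads of near-identical genes could therefore be shared, dropped or placed at random, which would alter the values of the myosin heavy chain, histocompatibility and ribosomal protein genes. FPKM is relative to all mapped reads, so a few very abundant muscle genes can shift the values of all other genes.

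The table held 24689 entries, most of them NCBI gene numbers. By gene number, 21743 matched a reference gene table of the goat assembly ARS1.2, and 15302 of these had a symbol other than a LOC name. This table was used for names only, and no coordinates were used. A further 603 entries were named as new loci by the authors, and 4264 had no product text. Entries with the same name were summed, which concerned 2 names. Members of the gene lists were matched by gene number and otherwise by product text, which added 53 members. MYH7 and MYOD1 had no entry of that name and were not analysed here.

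Depth was worked out from the FPKM values. Among entries above 0 in all 3 libraries, the ratios between libraries fell on fixed steps, from which whole reads and whole gene lengths were recovered. A value counted as whole within 5e-05 of a read, plus a rounding allowance of 6e-10. All 16054 entries above 0 in 3 libraries and 1157 above 0 in 2 gave whole reads, while the 1655 above 0 in a single library could not be resolved and 5823 were at 0 throughout. The totals behind the FPKM values were 15829474, 14920689 and 18399385 for kid, youth and adult, and the recovered reads made up 95.3%, 94.9% and 96.3% of them. The median recovered length was 1906 bases. The floor of 3 reads in a gene of 1 kb was 0.190, 0.201 and 0.163 FPKM. When 3 libraries were simulated from these totals and lengths, 93.2% of 16133 entries returned exactly the simulated reads. In the rest, reads and length share a common factor, so that fewer reads can be returned and the interval is then wider.

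Differences were taken on the scale of log2(FPKM + 1) among 12120 genes with a mean of at least 1 FPKM over the 3 libraries. This scale understates the difference of low genes, so ratios of FPKM are given beside it. A gene was counted as 2-fold apart where the difference was at least 1 on the log2 scale. Each ratio has an exact 95% interval of the 2 libraries' reads, which compares those libraries and not the stages. With 1 library per stage no test between stages was possible, and no p-value was computed.

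Before the data were examined, 33 lists with 731 genes were fixed, together with the comparisons, the thresholds and the alternatives. For each list with at least 5 members among the 12120 genes, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list lay outside the limits below percentile 2.5 or above 97.5. Such a percentile is a description of these libraries. With fewer random lists, and for youth against kid only, the procedure gave 6.67% of 270 list placements outside the limits in simulated libraries. These libraries held counting noise alone, drawn for each gene independently, and the same lists were placed in each simulation. Of the lists, 27 were large enough.

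The steps were tested on simulated reads drawn from the recovered means and totals. These hold counting noise alone and no variation between animals, so they do not show how many genes would differ between animals of the same age. With no difference, 12104 genes and 20 simulations, the median number of genes at least 2-fold apart was 9 for youth against kid, 6 for adult against youth and 7 for adult against kid. The highest numbers were 15, 11 and 15. With known folds in youth against kid (12098 genes, 50 genes per fold), 2%, 74%, 92% and 98% of genes were counted as 2-fold apart at true folds of 1.5, 2.5, 4 and 8. The interval left out 1 for 84%, 96%, 98% and 100% of them.

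Genes were named by a rule fixed beforehand. In each comparison it took the 8 highest and the 8 lowest differences among genes with a symbol and at least 5 FPKM in one of the libraries compared. From each list it took up to 3 members with the largest difference, at a minimum of 1 FPKM, and the most abundant member. It added the 5 highest and 5 lowest genes that differed in the same direction by at least 1.5-fold at both steps, the 5 most abundant genes per library, and a fixed set that included myosin heavy chain, myogenic, growth factor, collagen, fat-cell and milk genes. The text names those that serve its account. Some genes that the rule took are not reported here.

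The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 FPKM, rescaling to a larger common sum (which also makes the pseudocount smaller relative to the values), scaling by median ratios, quantile normalization, rescaling without the 50 most abundant genes, the highest entry in place of the sum, unmatched random lists and the mean in place of the median of a list. Requiring the counting interval, rescaling to the mean sum of the libraries, matching members by gene number alone, and taking off the trend with gene length and expression were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.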

Results

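Messenger RNA was measured by RNA sequencing in the longissimus dorsi, the long muscle along the spine, of goats (Capra hircus) at 3 postnatal stages: kid (2 months), youth (9 months) and adult (24 months). Each stage had 1 library. Whether a library came from 1 animal or from a pool, and the sex and breed of the animals, are not given in the sources used here. There were no replicates, so no difference reported here has a replicate check, no test was run, and each value describes these libraries rather than the stages. The comparisons address which genes differ in this muscle between the libraries of these stages. The deposited values were FPKM (fragments scaled to gene length and to the mapped total). The totals behind them, worked out from the smallest steps between values, were 15829474 for kid, 14920689 for youth and 18399385 for adult. A single read in a gene of 1 kb was worth 0.0632, 0.0670 and 0.0543 FPKM in the 3 libraries. Ratios between libraries are given with exact 95% intervals of the underlying reads, which cover counting error only. Across 12120 genes with a mean of at least 1 FPKM, Pearson's r of log2(FPKM + 1) was 0.986 between youth and kid, 0.976 between adult and youth and 0.979 between adult and kid. These correlations are across genes, which are not independent replicates.

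All 3 libraries were dominated by transcripts of striated muscle. Muscle creatine kinase (CKM, gene 102170262), which buffers ATP in contracting fibres, stood at 14183 FPKM in kid, 19069 in youth and 18998 in adult. Skeletal alpha-actin (ACTA1, gene 102182476), the thin-filament protein, stood at 14480, 17994 and 21435 FPKM in the same order. An uncharacterized gene (102180328) was about as abundant, at 18708, 17826 and 18175 FPKM. The glycolytic enzyme aldolase A (ALDOA) was at 9622, 9933 and 9261 FPKM, and the fast regulatory light chain MYLPF at 10021, 8969 and 10260. The 10 most abundant genes held 19.3%, 21.3% and 22.2% of all FPKM in kid, youth and adult. The protocol label names mammary tissue as the source of the RNA, while the tissue label names longissimus dorsi. The milk protein genes CSN2, CSN3 and LALBA were listed at 0 in all 3 libraries.

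The adult myosin heavy chain genes stood in a different order in the adult library than in the kid and youth libraries. MYH1 (gene 102181426), the heavy chain of fast type 2X fibres, was at 4693 FPKM in kid, 5942 in youth and 2636 in adult. MYH2 (gene 102181155), the heavy chain of the more oxidative type 2A fibres, was at 3054, 2248 and 3887 FPKM. MYH1 was 2.25-fold lower in adult than in youth (interval 2.24 to 2.27), and MYH2 was 1.73-fold higher (1.72 to 1.74). MYH4, the type 2B heavy chain, was low throughout, at 1.63, 1.06 and 0.219 FPKM. The embryonic MYH3 and perinatal MYH8 heavy chains were at 6.05, 5.73 and 8.83 FPKM and at 1.49, 1.63 and 2.00 FPKM. Myosin heavy chain genes are close copies, and how reads matching several of them were counted is not given in the sources used here, so single values of this family are uncertain. As whole lists, 14 slow-fibre contractile genes and 27 sarcomere genes lay within the range of random lists in all 3 comparisons.

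**Figure D1:**
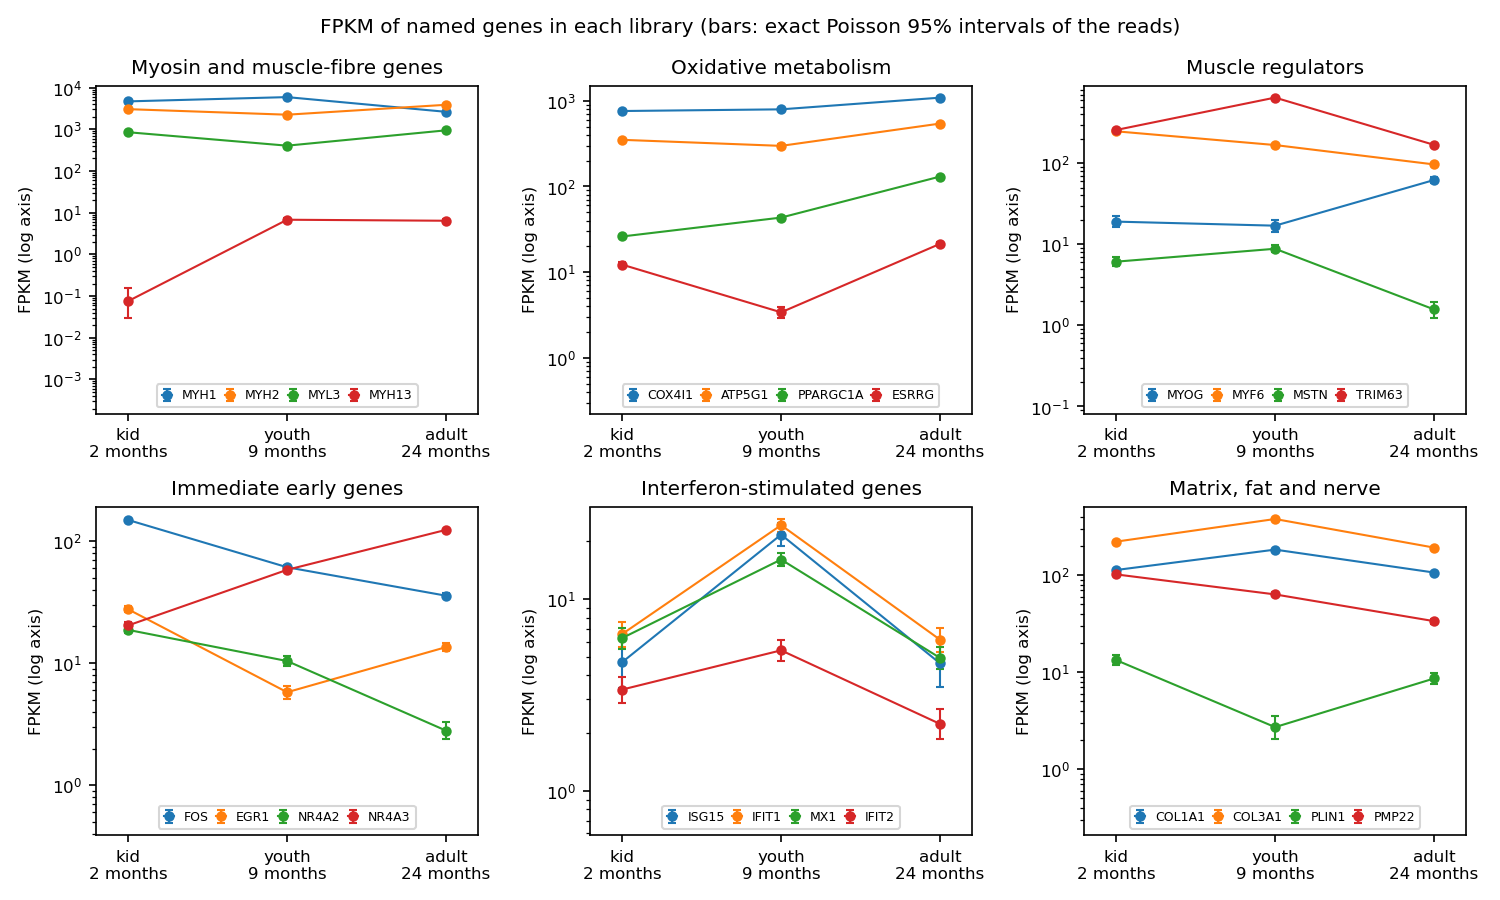
FPKM (log axis) of 24 genes in the kid, youth and adult libraries, with 1 point per library, bars for exact Poisson 95% intervals of the reads and lines joining the points of a gene. MYH1 was above MYH2 in kid and youth and below it in adult (2636 against 3887 FPKM), and ISG15 was at 21.6 FPKM in youth against 4.69 in kid and 4.62 in adult.

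Youth was compared with kid to see what differs between the libraries at 2 and 9 months. Interferon-stimulated genes were higher in the youth library: ISG15, a ubiquitin-like modifier, was at 21.6 against 4.69 FPKM (4.62-fold, 3.36 to 6.46), IFIT1, which binds viral RNA, was 3.69-fold higher (3.12 to 4.39), and the antiviral GTPase MX1 was 2.56-fold higher (2.21 to 2.99). Genes of collagens and extracellular matrix were also higher, among them COL3A1 at 379 against 221 FPKM (1.71-fold, 1.68 to 1.74), COL1A1 (1.62-fold, 1.58 to 1.66) and POSTN (3.86-fold, 2.52 to 6.10). Immediate early genes, which are induced within minutes of a stimulus and many of which encode transcription factors, were lower. EGR1 was at 5.78 against 27.6 FPKM (4.78-fold lower, 4.17 to 5.50), JUNB was 2.93-fold lower (2.43 to 3.55) and FOS 2.44-fold lower (2.31 to 2.57). Fat-cell genes were lower too, with the lipid-droplet coat protein PLIN1 at 2.72 against 13.3 FPKM (4.90-fold, 3.66 to 6.67) and the hormone adiponectin (ADIPOQ) 2.64-fold lower (2.44 to 2.86).

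Of 21 interferon-stimulated genes, 17 were higher in youth, 15 of them beyond counting error, and the list's median difference was 0.55 on the log2(FPKM + 1) scale, at percentile 100 of 10000 random lists matched on mean expression. The collagen and matrix list had 26 of 34 members higher (median 0.21, percentile 100). Of 23 immediate early genes 19 were lower (median -0.57, percentile 0), while the nuclear receptor NR4A3 was among the 4 that were higher, at 2.85-fold (2.66 to 3.06). The adipocyte list had 17 of 22 members lower (median -0.33, percentile 0.01), 5 of them at least 2-fold. Genes of Schwann cells, which wrap the nerve fibres in muscle, were lower in 6 of 6 cases (median -0.66, percentile 0), among them PMP22 at 63.3 against 102 FPKM. Ribosomal protein genes were lower in 54 of 57 cases (median -0.22, percentile 0), with RPS29 at 793 against 1269 FPKM. Genes of this family have many near-identical copies, so single values are uncertain for the same reason as in the myosin family, and the same holds for the genes of antigen presentation. Nuclear genes of oxidative phosphorylation were lower in 40 of 45 cases (median -0.19, percentile 0.12), and those of fatty acid oxidation in 22 of 28 (median -0.23, percentile 0). Fast-fibre contractile genes (median 0.17, percentile 99.8, 9 of 13 higher) and genes of glycolysis and glycogen (median 0.10, percentile 99.9, 19 of 28 higher) stood above the random lists, the fast-fibre genes not after quantile normalization (percentile 96.3). Fibroblast markers had a median of -0.20 (11 of 13 lower, percentile 1.93), which lay within the limits under 4 of 11 alternatives, for example at percentile 6.32 of unmatched lists. Altogether 11 of 27 lists lay outside the limits. In libraries simulated with counting noise alone, drawn for each gene independently, 6.67% of lists did. Genes of a list can vary together between animals, so this share is no baseline for such differences. Genes of T and natural killer cells (median 0.08, 5 of 6 higher, percentile 93.3) and of macrophages and monocytes (median -0.09, 6 of 13 higher, percentile 53.2) were inside the random range, with CD3E at 4.05 against 2.61 FPKM (1.55-fold, 1.08 to 2.24) and CD3G at 1.72 against 0.906 FPKM (1.90-fold, 1.22 to 2.999), while the other 4 genes of that list were not beyond counting error. The median over all 12120 genes was -0.08, and 1399 of them were higher and 3266 lower beyond counting error.

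Several single genes stood far apart between the youth and kid libraries. MYH13 (gene 102180345), a heavy chain best known from the muscles of the eye and larynx, was at 6.79 FPKM from 591 reads against 0.0758 FPKM from 7 reads in kid (89.6-fold, 43.2 to 224), and at 6.42 FPKM in adult. Single values of the myosin family are uncertain for the reason given above, and this holds for MYH13. The calcium buffer parvalbumin (PVALB) was at 11.7 against 1.33 FPKM (8.84-fold, 4.84 to 17.7), and the light chain MYL6B at 1338 against 410 FPKM (3.26-fold, 3.16 to 3.37). The methyltransferase gene METTL21C was 3.63-fold higher (3.33 to 3.97), and TRIM63, the ubiquitin ligase MuRF1 that marks sarcomere proteins for breakdown, was 2.51-fold higher at 644 against 257 FPKM (2.44 to 2.58). Lower in youth were the cell cycle inhibitor CDKN1A (3.21-fold, 2.82 to 3.67) and ESRRG, an orphan nuclear receptor that drives oxidative genes (3.60-fold, 3.09 to 4.22). FAM180A was 5.90-fold lower (4.37 to 8.12). In adult, CDKN1A was at 15.7 FPKM against 20.5 in youth and FAM180A at 2.99 against 2.53, while ESRRG was at 21.4 against 3.40. IGF1, the growth factor, was at 12.4 against 23.8 FPKM (1.91-fold lower, 1.63 to 2.24). In all, 51 genes were at least 2-fold higher and 76 at least 2-fold lower on the log2(FPKM + 1) scale, of which 49 and 71 were also beyond counting error, and 5 and 7 differed at least 4-fold. After quantile normalization the split was 62 higher and 56 lower. Libraries simulated with counting noise alone, and so without differences between animals, gave a median of 9 such genes (at most 15 in 20 simulations). The total of 127 was 300 with a pseudocount of 0.1, 45 with a pseudocount of 5 and 64 among genes with a mean of at least 5 FPKM.

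**Figure D2:**
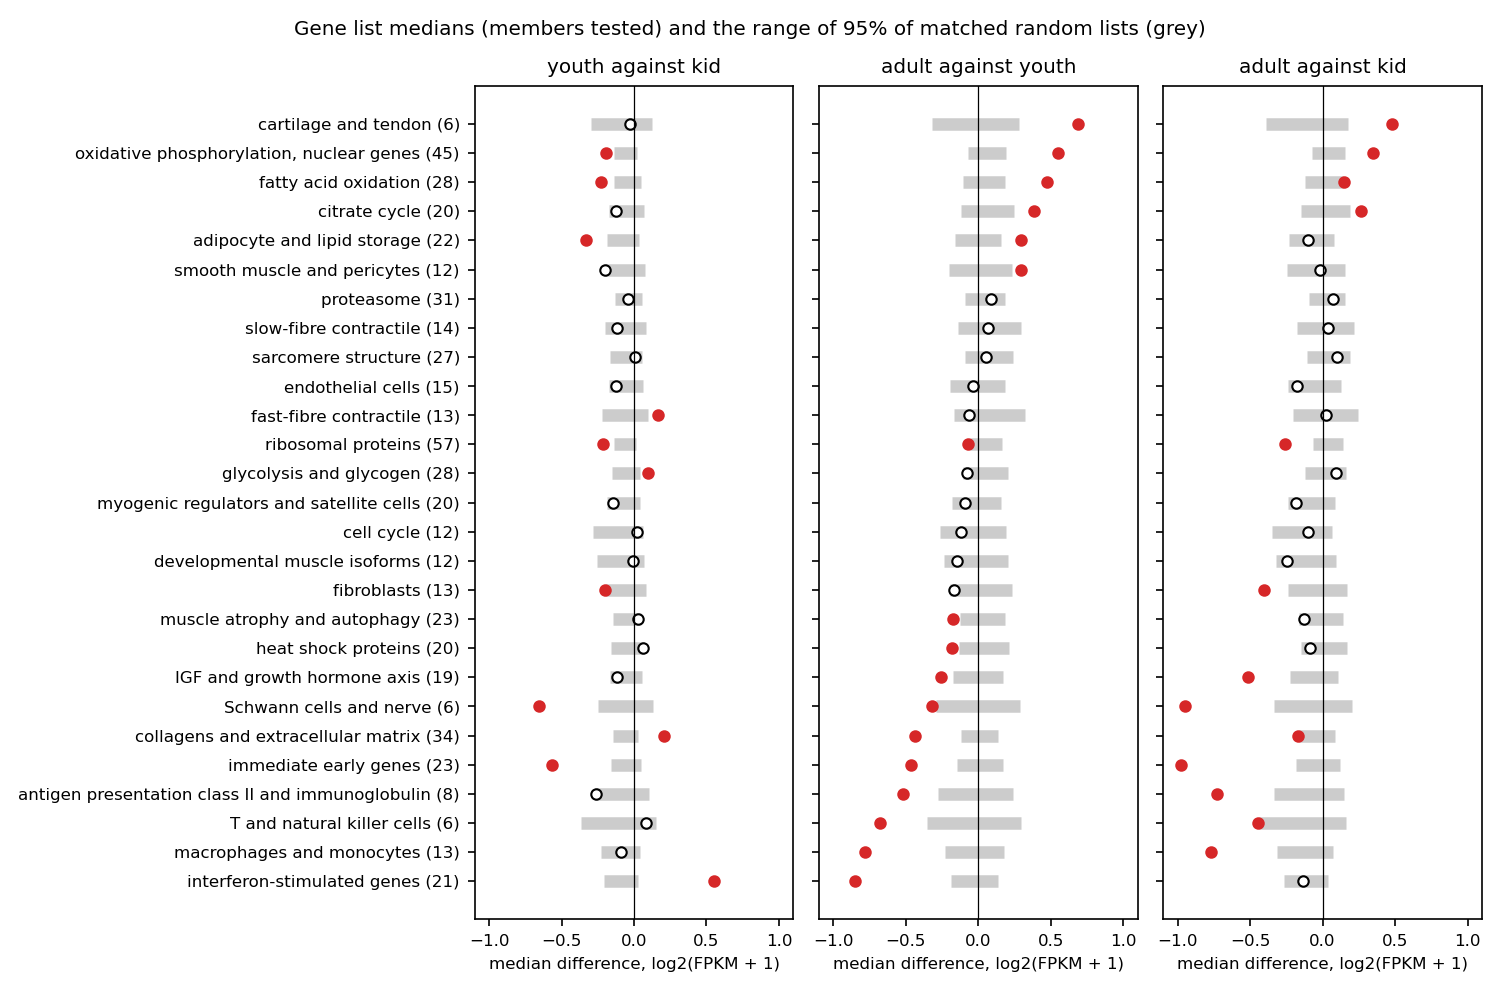
Median difference of log2(FPKM + 1) of 27 gene lists in the 3 comparisons (horizontal axis), with the number of members tested in brackets. Grey bars span 95% of the random lists, filled points lie outside that range and open points inside. Oxidative phosphorylation genes were at -0.19 in youth against kid and at 0.55 in adult against youth, while immediate early genes were below 0 in all 3 comparisons.

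Adult was compared with youth to see what differs between the libraries at 9 and 24 months. All 45 of 45 tested nuclear genes of oxidative phosphorylation were higher in the adult library, each beyond counting error. Over all 12120 genes, 2706 were higher and 3273 lower beyond counting error. ATP synthase subunit ATP5G1 was at 542 against 298 FPKM (1.82-fold, 1.74 to 1.90) and COX7A1 at 160 against 87.5 FPKM (1.82-fold, 1.71 to 1.95). PPARGC1A (gene 100861288), a coactivator that drives the making of mitochondria, was at 130 against 43.3 FPKM (3.01-fold, 2.90 to 3.13), and ESRRG at 21.4 against 3.40 FPKM (6.30-fold, 5.45 to 7.32). Genes of immune cells and of the matrix were lower: C1QA, a complement protein made by macrophages, was 2.46-fold lower (1.99 to 3.05) and COL3A1 1.97-fold lower (1.94 to 2.01). Interferon-stimulated genes were also lower, ISG15 4.69-fold (3.47 to 6.43) and IFIT1 3.95-fold (3.35 to 4.68). Since the youth library enters both comparisons, anything particular to it appears in both with opposite sign.

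The oxidative phosphorylation list had a median of 0.55 (percentile 100), fatty acid oxidation 0.47 (25 of 28 higher, percentile 100) and the citrate cycle 0.39 (19 of 20 higher, percentile 99.9). An exception was PDK4, the kinase that shuts the pyruvate dehydrogenase complex, at 642 against 1498 FPKM (2.33-fold lower, 2.31 to 2.36). Myoglobin (MB), which stores oxygen in fibres, was at 12064 against 8234 FPKM (1.47-fold, 1.46 to 1.48). The glucose transporter SLC2A4 was 2.44-fold higher (2.31 to 2.58) within a glycolysis and glycogen list that as a whole lay inside the random range (median -0.08, percentile 6.09). In that list PFKFB3, which makes an activator of glycolysis, was 5.10-fold lower (4.72 to 5.51). Slow-fibre genes were not apart as a list (median 0.07, percentile 60.2), though the light chain MYL3 was 2.33-fold higher (2.24 to 2.44) and the stretch-responsive ANKRD2 3.51-fold higher (3.26 to 3.77). Adipocyte genes were higher in 17 of 22 cases (median 0.29, percentile 99.97). Of these, 2 were at least 2-fold higher, PLIN1 at 8.61 against 2.72 FPKM and the desaturase SCD at 11.5 against 5.19 FPKM. FABP4 was at 65.8 against 68.7 FPKM, a ratio of 0.959 with an interval that included 1 (0.827 to 1.11). Smooth muscle and pericyte genes were higher in 10 of 12 cases (median 0.29, percentile 99.2), for example MYH11 (1.91-fold, 1.79 to 2.03). Cartilage and tendon genes had a median of 0.69 (percentile 99.99) over 6 members. The tendon markers TNMD (20.6-fold, 8.60 to 64.5, 127 against 5 reads) and COMP (11.9-fold, 7.75 to 19.3, 324 against 22 reads) were higher, while CHAD and KERA were lower.

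Lower in adult were 19 of 21 interferon-stimulated genes (median -0.85, percentile 0), 13 of 13 macrophage and monocyte genes (median -0.78, percentile 0), 6 of 6 genes of T and natural killer cells (median -0.68, percentile 0.02) and 7 of 8 genes of class II antigen presentation (median -0.52, percentile 0.03). The collagen and matrix list was lower in 29 of 34 cases (median -0.44, percentile 0), and immediate early genes in 19 of 23 (median -0.46, percentile 0), although JUNB was 3.29-fold higher (2.75 to 3.97), EGR1 2.34-fold (2.02 to 2.72) and NR4A3 2.12-fold (2.04 to 2.22). The insulin-like growth factor axis was lower in 13 of 19 cases (median -0.25, percentile 0.17), with IGF2 at 24.7 against 44.7 FPKM and the binding protein IGFBP5 at 19.05 against 46.8 FPKM, while IGF1 was 1.27-fold higher (1.08 to 1.51). Genes of muscle atrophy and autophagy were lower in 18 of 23 cases (median -0.17, percentile 0.64, but 2.97 among unmatched random lists): TRIM63 was at 168 against 644 FPKM (3.83-fold lower, 3.71 to 3.95), and FOXO1, a transcription factor upstream of it, at 14.3 against 56.2 FPKM (3.92-fold lower, 3.68 to 4.17). Heat shock genes had a median of -0.18 (13 of 20 lower, percentile 0.55, but 3.05 among unmatched lists), with HSPB6 the other way at 901 against 397 FPKM. Ribosomal protein genes (median -0.07, 43 of 57 lower, percentile 0.81) were inside the range of unmatched random lists (percentile 16.3). Schwann cell genes (median -0.32, 5 of 6 lower, percentile 1.65) lost their place outside the limits under 4 of 11 alternatives.

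Among regulators of muscle growth, myogenin (MYOG, gene 100861395), which drives terminal differentiation, was at 62.0 FPKM in adult against 17.0 in youth and 19.03 in kid (3.65-fold over youth, 3.04 to 4.42). Myostatin (MSTN, gene 100860887), which restrains muscle mass, was at 1.57 against 8.81 FPKM in youth and 6.10 in kid (5.60-fold below youth, 4.38 to 7.22). MYF6 was 1.73-fold lower in adult than in youth (1.64 to 1.83), and the satellite cell gene PAX7 was at 1.97 against 0.901 FPKM (2.19-fold, 1.29 to 3.86). The list of myogenic regulators as a whole was not apart (median -0.09, percentile 17.8). PARM1 was 7.17-fold higher in adult (5.78 to 8.98), the potassium channel KCNN1 6.83-fold higher (4.54 to 10.7) and RNASE13 10.8-fold higher (6.40 to 19.7). ARID5B was 5.47-fold lower (5.14 to 5.83), CSRNP1 4.51-fold lower (4.03 to 5.06) and PVALB 9.49-fold lower (5.30 to 18.4). This pair of libraries had the most genes at least 2-fold apart, 122 higher and 130 lower, against a median of 6 in simulations of counting noise alone. Of these, 121 and 128 were beyond counting error, 12 and 11 were at least 4-fold apart, and 17 of 27 lists lay outside the random range, 6 above and 11 below. The total of 252 was 555 with a pseudocount of 0.1, 82 with a pseudocount of 5, 160 at a mean of at least 5 FPKM, and 386 (138 higher, 248 lower) after rescaling to a larger common sum, which also made the pseudocount smaller relative to the values. With the libraries brought to their mean sum, which left the pseudocount at its size, it was 274 (108 higher, 166 lower).

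**Figure D3:**
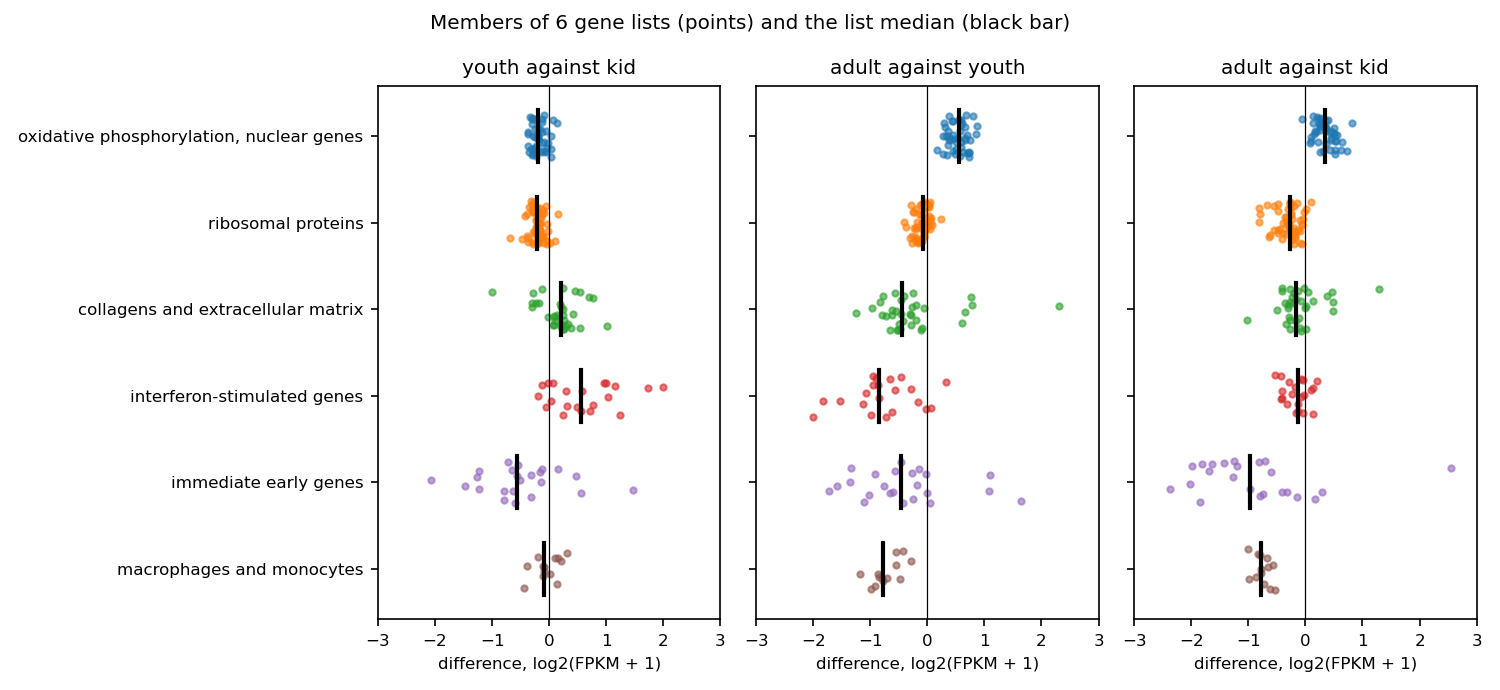
Differences of log2(FPKM + 1) of the members of 6 gene lists (points, spread vertically at random) and the list medians (black bars) in the 3 comparisons. In adult against youth every one of the 45 oxidative phosphorylation genes lay above 0, and the 13 macrophage and monocyte genes all lay below 0.

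Adult was compared with kid to see what differs between the libraries at 2 and 24 months. Oxidative phosphorylation genes were higher in the adult library in 44 of 45 cases (median 0.35, percentile 100), with CYCS, the electron carrier cytochrome c, at 430 against 243 FPKM (1.77-fold, 1.69 to 1.85). PPARGC1A was 5.005-fold higher (4.79 to 5.24) and myoglobin 1.72-fold higher (1.71 to 1.73). Immediate early genes were lower in 20 of 23 cases (median -0.98, percentile 0), and 11 of them at least 2-fold: FOS was at 35.7 against 149 FPKM (4.17-fold lower, 3.93 to 4.43) and NR4A2 at 2.80 against 18.7 FPKM (6.68-fold lower, 5.65 to 7.94). Genes of Schwann cells were lower in 6 of 6 cases (median -0.95, percentile 0), with PMP22 3.03-fold lower (2.83 to 3.25). Ribosomal protein genes were lower in 55 of 57 cases (median -0.26, percentile 0), among them RPL26 at 432 against 750 FPKM and RPL3 at 74.9 against 132 FPKM.

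The citrate cycle (median 0.26, 18 of 20 higher, percentile 99.8), fatty acid oxidation (median 0.15, 22 of 28 higher, percentile 98.2) and cartilage and tendon lists (median 0.48, 4 of 6 higher, percentile 100) were above the random lists, the last of these not without a filter on low values (median 0.035, percentile 94.1). Below them were macrophages and monocytes (median -0.77, 13 of 13 lower, percentile 0), class II antigen presentation (median -0.73, 8 of 8 lower, percentile 0), fibroblasts (median -0.40, 13 of 13 lower, percentile 0.02) and the insulin-like growth factor axis (median -0.52, 15 of 19 lower, percentile 0). In the last of these, IGF1 was at 15.9 against 23.8 FPKM (1.498-fold lower, 1.30 to 1.72) and SOCS3, which dampens cytokine signals, was 2.85-fold lower (1.71 to 4.92). T and natural killer cell genes (median -0.45, 6 of 6 lower, percentile 2.18) and the matrix list (median -0.17, 25 of 34 lower, percentile 2.10) were within the limits under 4 of 10 and 5 of 11 alternatives, the matrix list at percentile 32.8 once trends with gene length and expression were taken off. Interferon-stimulated genes (median -0.13, percentile 41.0) and adipocyte genes (median -0.10, percentile 35.4) were inside the random range in this comparison, although single adipocyte genes such as FABP4 were lower (2.45-fold, 2.17 to 2.76). The muscle acetylcholine receptor subunit CHRNA1 was at 2.06 against 9.38 FPKM (4.56-fold lower, 3.35 to 6.31).

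Genes that differed in the same direction by at least 1.5-fold at both steps were few, with 5 higher and 19 lower. Those higher included NR4A3 (20.4, 58.2 and 124 FPKM in kid, youth and adult), PPARGC1A (26.1, 43.3 and 130), NT5DC3 (9.02, 17.7 and 49.1) and ANGPTL4 (20.04, 31.1 and 47.9), an inhibitor of lipoprotein lipase. Those lower included the deubiquitinase OTUD1 (204, 96.9 and 32.4), FOS, FOSL2 (58.2, 37.3 and 14.0) and NR4A2. In addition 39 genes were at least 2-fold higher in adult than in both other libraries and 50 at least 2-fold lower. For youth these numbers were 23 and 25, and for kid 24 and 10. Between adult and kid, 65 genes were at least 2-fold higher and 148 lower, 64 and 145 of them beyond counting error, where libraries simulated with counting noise alone gave a median of 7. The total of 213 was 451 with a pseudocount of 0.1, 71 with a pseudocount of 5 and 122 at a mean of at least 5 FPKM. The split was 82 higher and 112 lower after median-ratio scaling, and 90 of 191 were higher after quantile normalization.

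Markers of other cell types were low next to muscle genes and differed from list to list. Endothelial genes were not apart in any comparison, with PECAM1 at 72.7, 65.3 and 54.1 FPKM in kid, youth and adult. Haemoglobin alpha (HBA1) was at 1.02, 1.08 and 1.37 FPKM, from 9, 9 and 14 reads. The 12 of 34 cell cycle genes with a mean of at least 1 FPKM were also within the random range. The proliferation marker MKI67 was too low to be among them, at 0.233, 0.627 and 0.0976 FPKM, from 39, 99 and 19 reads. It was 2.69-fold higher in youth than in kid (1.84 to 4.01) and 6.43-fold lower in adult than in youth (3.91 to 11.1). Proteasome genes were within the range in all 3 comparisons, as were developmental muscle isoforms. Of the 27 lists, 13 lay outside the range in adult against kid, 4 above and 9 below.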

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

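The requirement of a counting interval, rescaling to the mean sum, the matching of members by gene number alone and the removal of the length and expression trend were chosen after seeing the data. The numbers of genes at least 2-fold apart (127 for youth against kid, 252 for adult against youth and 213 for adult against kid) were 300, 555 and 451 with a pseudocount of 0.1 and 45, 82 and 71 with a pseudocount of 5. They were 64, 160 and 122 at a mean of at least 5 FPKM, where fewer genes were tested. Rescaling to a larger common sum, which also made the pseudocount smaller relative to the values, gave 186, 386 and 319. The mean sum, with the pseudocount at its size, gave 126, 274 and 224. For adult against youth the split of 122 and 130 was 138 and 248 with the first and 108 and 166 with the second. For adult against kid the split of 65 higher and 148 lower was 82 and 112 with median ratios and 90 higher of 191 with quantile normalization. For youth against kid, 51 and 76 were 62 and 56 with quantile normalization. Without a filter, 17 of 32 lists in place of 11 of 27 lay outside the limits in youth against kid, where more lists reached the minimum size. Of 41 list differences outside the limits, 32 stayed there under every alternative that gave a value, and 9 did not under 1 or more. No value in the comparisons changed sign where it had been counted as apart. Pearson's r at a mean of at least 5 FPKM was 0.985, 0.969 and 0.972, and Spearman's rho was 0.980, 0.966 and 0.971. Leaving out each column in turn was not run, since each stage had 1 column. No paired analysis was possible because each stage had 1 library. Depth limits low genes: PVALB rested on 12 reads in kid and 13 in adult.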

Other observations

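The test on length and expression bias was specified before its result was seen, and the tests on macrophages, on T and natural killer cells, on non-muscle cells, on the animal sampled, on genes described as like another gene and on reads placed on other copies were chosen only after the result was seen.

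Albumin (ALB), the main plasma protein made by liver, was at 5.37 FPKM in kid (176 reads), 0.162 in youth (5 reads) and 0.918 in adult (35 reads). Fibrinogen beta (FGB) was at 1.51, 0.0349 and 0.141 FPKM from 46, 1 and 5 reads, and its ratio of kid to youth was 43.4 (7.40 to 1749). Transferrin (TF) was 2.67-fold higher in kid than in youth (1.90 to 3.80), and the neutrophil proteins S100A12 2.90-fold higher (1.55 to 5.73) and S100A8 5.03-fold higher (1.44 to 26.9, 16 against 3 reads), while for S100A9 the ratio of 2.24 had an interval that included 1 (0.936 to 5.91). The liver, neutrophil and skin lists had 3 members each at a mean of 1 FPKM, the red cell and the mammary lists 1 and the mitochondrially encoded list 0, too few to be placed among random lists.

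XIRP2, an actin-binding protein, was at 403, 200 and 399 FPKM in kid, youth and adult, SMPX at 700, 437 and 840, and the M-band protein MYOM3 at 69.3, 41.8 and 72.5. The Notch target HES1 was at 35.1, 15.8 and 30.8 FPKM, while the growth factor receptor MET was at 7.67, 15.5 and 6.29. ZNF385B was 6.08-fold higher in youth than in kid (4.68 to 8.005) and 4.27-fold lower in adult than in youth (3.45 to 5.32). TP63, a relative of p53, was 2.52-fold lower in adult than in youth (2.19 to 2.90).

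Interferon-stimulated genes had a median of 0.55 in youth against kid. For more leukocytes in the youth piece, the threshold was a rise of their genes by at least 0.27, chosen as a share of that median. The 13 macrophage and monocyte genes had a median of -0.087 (95% bootstrap interval over genes -0.11 to 0.14), below the threshold. A smaller contribution was not tested, and the interval holds no spread between animals. More T and natural killer cells stayed open, since their 6 genes had a median of 0.085 with an interval of -0.044 to 0.50 and 2 were higher beyond counting error while 4 were not (the 19 were first tested jointly, at 0.022). After the trend with gene length and expression was taken off, the interferon median was 0.64 (0.30 to 1.09), above the random lists' limit of 0.12, so that trend was not the whole cause. The state of the animal sampled may be a candidate explanation, and it cannot be told apart from age with 1 library per stage. In adult against youth, the medians of the interferon (-0.85), macrophage and monocyte (-0.78) and T and natural killer cell (-0.68) lists were all negative.

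Oxidative phosphorylation genes had a median of 0.55 in adult against youth. For fewer non-muscle cells in the adult piece, the threshold was a rise of other fibre genes by at least 0.27, chosen as a share of that median. The 55 sarcomere and glycolysis genes had a median of 0.032 (bootstrap interval over genes -0.10 to 0.18), below the threshold. The sarcomere list alone was at 0.05 (19 of 27 higher) and the glycolysis and glycogen list at -0.08. A smaller contribution was not tested, and the interval holds no spread between animals. After the trend with length and expression was taken off, the oxidative phosphorylation median was 0.41 (0.33 to 0.51), against the random lists' limit of 0.13. The state of the animal sampled rather than its age may also be the source, and with 1 library per stage these cannot be told apart. Age itself remains a hypothesis.

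Among genes with recovered reads and at least 100 in a library, 7 differed at least 16-fold between libraries, with fewer than 3 reads counted as 3. The 1655 entries above 0 in a single library had no recovered reads and could not enter. The entries among the 7 outside the naming rule were chosen after their values were seen. These were a class I histocompatibility entry (102177715; 44.5, 65.4 and 0 FPKM in kid, youth and adult), LOC102179937 (class II DQ alpha-like; 0, 5.66 and 1.05), LOC102186300 (BTF3-like; 26.6, 2.86 and 1.37) and LOC102190429 (ribosomal protein S25-like; 0.257, 0.409 and 34.7), beside ALB, MYH13 and TNMD. Of the 7, 57.1% (exact interval 18.4 to 90.1) were described as like another gene, against 11.7% of 9732 genes with as many reads. A larger share was the prediction for sequence differences between animals at near-identical copies. It was chosen after the result was seen, a product name does not measure how alike copies are, and no sequences were compared. The share therefore cannot decide this explanation. If reads of an entry were placed on its copies, those copies would differ the other way by as many reads. Differences were taken as the library where the entry was highest minus the one where it was lowest. The copies differed by -79.1 reads per 10000000 for DQ alpha against 70.4 for the entry itself, and by 77.0 for class I against 212 (with 1 copy at -70.5). They differed by 242 for BTF3-like against 160 for the entry, and by -1931 for S25-like against 169. With 1 library per stage the spread of these copies between animals was not measured, so for all 4 entries (tested first jointly and then singly) reads placed elsewhere cannot be told apart from other differences of the animal sampled or from age.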
